A study of Mus musculus with 12 samples.

How the data were processed

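Gene expression was measured by poly(A)-selected RNA sequencing in 12 libraries of wild-type mouse bone marrow-derived macrophages, 3 biological replicates in each of 4 groups. The groups were medium alone (M), itaconic acid (IA), malonic acid (MA) and methylsuccinic acid (MetSA), each compound at 5 mM from a 50 mM stock for 16 h. Group and replicate number were taken from the sample titles. The protocols name selection with oligo(dT) beads and random hexamer priming, and give no statement on strand, so reads of overlapping and antisense genes cannot be assigned with certainty.

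The deposited values are whole-number counts per gene that were not normalised by the authors. Per the submitters' processing notes, STAR, featureCounts and the mm10 build were used, and their versions and the annotation are not given in the sources used here. The table held 32285 genes, all 12 value columns were matched to a sample by name, and 32158 of the genes had a symbol. The 127 genes without a symbol took 0.0267% of the counts, and 26 symbols stood on several gene identifiers, which were kept as separate genes. Of counts from 1 to 9, 66.1% were even numbers, against 50.9% of counts of 1000 or more, and 13032 values equalled 2 where 5652 equalled 1. Both mates of a read pair may therefore have been counted for many fragments, so the depth in fragments lies below the count totals by an unknown factor, and a repeat with halved counts was run. Coordinates are those of the GENCODE M21 annotation on GRCm38 (mm10), 1-based.

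Library totals ran from 46892488 to 54252486 counts, with 16662 to 17246 genes above 0 and 8.63% to 11.2% of counts in the 10 most abundant genes. Replicates of each group were compared by a chi-square test over genes, and each library differed from the others of its group by more than sampling noise (chi-square per degree of freedom from 9.6 to 59.7), so none was treated as a library counted again. Genes were kept by filterByExpr with its defaults, which left 14113 genes holding 99.98% of the counts. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) on 1 fit of all 4 groups, with 8 residual degrees of freedom and no covariate, and 6 comparisons were made between groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Standard errors and 95% intervals come from the same fit. CPM values are normalised by the TMM library sizes, and errors after ± are SDs of 3 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

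Genes named in the text were chosen by a rule fixed before the data were examined, as were the groups, the tests of the comparisons, the gene lists and the alternatives other than those marked as added. The TGF-beta list, the genes named from it and the tests of the mitochondrial and interferon patterns in the closing observations came later. Ifnb1, which is on none of the lists and is not a key gene, was named outside that rule. For each compound against M the rule took the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between the 3 values of each group, skipping predicted genes and pseudogenes. It took 6 and 6 for each direct comparison and for genes that set a group apart, up to 4 members of each list with the smallest adjusted p, up to 2 members going against the list's median, and 26 key genes. With a gene counted once for each list that held it, the 29 lists held 615 entries. They cover the type I interferon response, NF-kB inflammatory genes, NRF2 targets, ATF4 and the integrated stress response, the unfolded protein response, heat shock, HIF-1 targets and glycolysis, the TCA cycle, nuclear and mitochondrial respiration genes, redox enzymes, itaconate metabolism, cholesterol and LXR genes, lysosome, p53, cell cycle, MYC, MHC class II, alternative activation, iron handling and markers of macrophages, osteoclasts, neutrophils, dendritic cells, lymphocytes, stromal cells, mast cells and erythroid cells. Mx1, Mx2 and Clec7a were on a list but are not analysed here.

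Lists with at least 5 tested members were tested by camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation, and by fry, each adjusted over the lists of a comparison. With an estimated correlation 0 of 11 list calls held for IA against M, 0 of 10 for MA against M, 2 of 11 for MetSA against M, 0 of 8 for IA against MA, 0 of 9 for IA against MetSA and 1 of 6 for MA against MetSA. Genes with shared sequence were found by matching 100-base stretches of annotated transcripts to those of other genes, and those with 10% or more shared are uncertain. Of the genes named below these include Ctsd (30.2%), Idi1 (21.9%), Tgm2 (15.5%) and Ccna2 (10.1%), besides Gbp6, Prdx5 and mt-Co1. Overlaps of calls were set against independent lists and against 20 simulations of unchanged groups with shared controls.

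Alternatives were RLE and upper-quartile scaling, no filter, a filter at 10 CPM in 3 libraries, DESeq2, limma-voom, a fit of the compared groups only, the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1 and leaving out each library in turn. Halved counts and a correction for transcript length and GC content were added after seeing the data, as were upper-quartile scaling for the list tests and the unfiltered fits for Il6 and Ifnb1. The steps were tested on simulated counts for the comparison of IA with M (13776 genes). Recovered were 61.2% of 67 genes changed 1.5-fold, 74.6% of 67 changed 2-fold and 89.4% of 66 changed 4-fold. Of 163 calls, 13 were genes left unchanged. The changed genes were a small part of those simulated, unlike in the real comparison. Some genes that the naming rule selected are not reported here.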

Results

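Poly(A)-selected RNA was sequenced from bone marrow-derived macrophages of wild-type mice, which are macrophages grown in culture from bone marrow precursors. The cells were kept for 16 h in medium alone (M) or in medium with a dicarboxylic acid at 5 mM. The acids were methylsuccinic acid (MetSA), malonic acid (MA) and itaconic acid (IA). Itaconic acid is a dicarboxylic acid that activated macrophages make with the enzyme Acod1, and it carries a carbon-carbon double bond as a methylene group on a succinic acid chain. Methylsuccinic acid has the same carbon skeleton without that double bond. Malonic acid is a shorter dicarboxylic acid and an inhibitor of succinate dehydrogenase. Each of the 4 groups held 3 biological replicates, so 12 libraries were compared. Whether the replicates came from separate animals is not given in the sources used here. The libraries held between 46892488 and 54252486 counts, and 14113 of the 32285 genes in the table had enough counts to be tested.

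The 3 libraries of each group lay together on the first principal components of log2 CPM (counts scaled to library size). The first component held 42.2% of the variance and set IA (42.0 to 45.0) and MetSA (15.3 to 30.1) apart from M (-31.2 to -23.3) and MA (-43.0 to -39.5). The second component held 15.3% and set M apart from MA. MetSA replicate 3 lay nearest to M among the MetSA libraries, at 15.3 on the first component, and stood apart on the third, which held 6.8%, at 32.7. Mitochondrially encoded genes took 1.24% of the counts on average in M, 0.757% in IA, 1.09% in MA and 0.957% in MetSA, where replicate 3 alone was at 1.28%. TMM scaling factors ran from 0.927 to 0.935 in IA and from 1.05 to 1.07 in M.

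**Figure D1:**
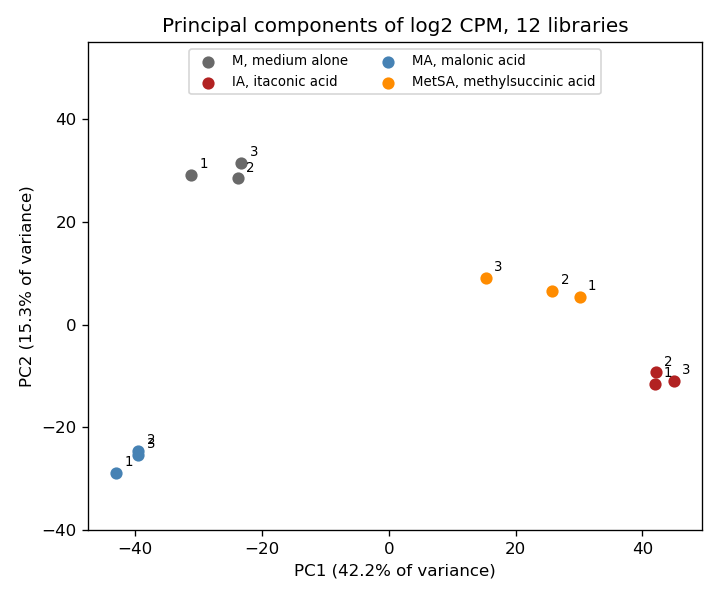
Scores of the 12 libraries on the first and second principal components of log2 CPM, coloured by group and numbered by replicate, with the percentage of variance on each axis. The IA libraries lie between 42.0 and 45.0 on the first component and the MA libraries between -43.0 and -39.5.

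The comparison of IA with M asked which transcripts differ in macrophages given itaconic acid. Interferon-stimulated genes led the rises among genes at 10 CPM or more. Slfn1, an interferon-inducible gene of the Schlafen family, rose from 2.42 ± 0.80 to 121 ± 13 CPM (SD, n = 3 in each group), a log2 fold change of 5.64 (SE 0.40, adjusted p = 5.55e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ifi44 rose from 7.73 ± 1.9 to 286 ± 37 CPM (log2 fold change 5.21, SE 0.29, adjusted p = 8.73e-07). Iigp1, a GTPase that acts on vacuoles holding pathogens, rose from 6.74 ± 1.2 to 205 ± 17 CPM (4.93, SE 0.34, adjusted p = 5.16e-06). In mm10 coordinates Slfn1 lies on chromosome 11 from 83116849 to 83122670 and Ifi44 on chromosome 3 from 151730922 to 151749960. Among the largest falls were Egr2, a transcription factor (log2 fold change -1.92, SE 0.11, adjusted p = 8.08e-11), and Dcstamp, a membrane protein needed for fusion of osteoclast precursors (-1.96, SE 0.17, adjusted p = 1.71e-06). They also held the gelatinase Mmp9 (-1.79, SE 0.16, adjusted p = 1.92e-07) and Cdc20, an activator of the anaphase-promoting complex (-1.73, SE 0.15, adjusted p = 2.68e-08). Ifi27, whose name marks it as interferon-inducible but which was outside the interferon list, fell by 1.76 (SE 0.26) on the log2 scale.

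All 33 tested members of the type I interferon list rose after IA, also when adjusted over the list alone, with a median log2 fold change of 2.79 (camera adjusted p = 5.89e-32, and adjusted p = 0.108 with an estimated correlation). Trim30a rose from 245 ± 22 to 919 ± 20 CPM (log2 fold change 1.91, SE 0.07, adjusted p = 3.72e-13 in edgeR's test), and the cytosolic RNA sensors Ddx58 and Ifih1 rose by 2.24 (SE 0.09) and 2.15 (SE 0.09). Of 26 cholesterol biosynthesis genes 22 rose and none fell, also 22 adjusted over the list alone, and the median was 0.64 (camera adjusted p = 8.32e-13, and adjusted p = 0.103 with an estimated correlation). The sterol demethylase Cyp51 went from 37.3 ± 4.6 to 86.4 ± 9.0 CPM (1.21, SE 0.08, adjusted p = 1.25e-09), and the early pathway enzyme Hmgcs1 rose by 1.09 (SE 0.08). Cell cycle genes fell, 33 of 36 over all genes tested and also adjusted over the list alone, with a median of -0.94 (camera adjusted p = 7.17e-16, and adjusted p = 0.108 with an estimated correlation). Ccna2, a cyclin of S phase and G2, fell by 1.30 (SE 0.11) on the log2 scale and Top2a, a topoisomerase of dividing cells, by 1.03 (SE 0.08). MYC and ribosome biogenesis genes followed with 17 of 22 lower, or 18 adjusted over the list alone, at a median of -0.46 (camera adjusted p = 3.66e-06, and adjusted p = 0.108 with an estimated correlation). Myc itself fell by 1.36 (SE 0.10).

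Inflammatory genes of the NF-kB list rose after IA on balance. Of 33 members 16 were higher and 1 lower, or 17 and 3 adjusted over the list alone, at a median of 0.27 (camera adjusted p = 0.00228, and adjusted p = 0.108 with an estimated correlation). The anti-inflammatory cytokine Il10 rose by 1.58 (SE 0.16), the interleukin-1 receptor antagonist Il1rn by 1.27 (SE 0.09) and the chemokine Ccl3 by 1.04 (SE 0.10). Nfkbiz, which encodes a nuclear regulator of secondary NF-kB targets, rose by 0.77 (SE 0.08, adjusted p = 4.9e-07 in edgeR's test), while Cxcl2, another chemokine, fell by 1.02 (SE 0.16). Among 21 unfolded protein response genes 14 rose and 2 fell, or 15 and 3 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.00036, and adjusted p = 0.314 with an estimated correlation). The chaperone Hspa5 rose from 873 ± 66 to 1600 ± 86 CPM (0.87, SE 0.06), and without IA replicate 1 no member fell. The p53 target list had 11 of 20 higher and 1 lower, or 12 and 1 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00036, and adjusted p = 0.108 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1a rose by 0.82 (SE 0.07). Macrophage markers had 11 of 16 higher, or 12 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.000112, and adjusted p = 0.103 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, rose from 307 ± 32 to 1750 ± 42 CPM (2.51, SE 0.13). The lysosome list (14 of 30 higher and 3 lower, or 14 and 6 adjusted over the list alone, median 0.11) had a camera adjusted p of 0.0231, and adjusted p = 0.712 with an estimated correlation. That call was lost without M replicate 2 (adjusted p = 0.0536) or IA replicate 1 (0.0637, median 0.06, 5 members lower) and under the stricter filter (0.117). Npc2, a lysosomal cholesterol carrier, rose by 1.19 (SE 0.08), whereas the proton pump subunit Atp6v0d2 fell by 1.29 (SE 0.11).

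Mitochondrially encoded mRNAs were lower after IA, with 6 of 12 members called lower, also 6 adjusted over the list alone, and none higher (median -1.05, camera adjusted p = 0.0058, and adjusted p = 0.522 with an estimated correlation). Without IA replicate 2 the median was -0.48. Another 5 members, with 90% or more of their sequence in another gene, had at most 203 counts in any library. These hardly measured members enter the list median in each comparison. Osteoclast markers had 4 of 7 lower and 1 higher, or 5 and 1 adjusted over the list alone, with a median of -1.17 (camera adjusted p = 0.0438, and adjusted p = 0.396 with an estimated correlation). The member that rose was the acid phosphatase Acp5 (0.89). The osteoclast call was lost without M replicate 2 (adjusted p = 0.0536), M replicate 3 (0.0598) or IA replicate 1 (0.0576). It was lost too with upper-quartile scaling (0.11), a length and GC correction (0.0828) and the replicate number as a block (0.0596). The NRF2 target list, which holds antioxidant and glutathione genes, was not called, with 3 of 30 members higher and 7 lower, or 3 and 6 adjusted over the list alone (median -0.09, camera adjusted p = 0.391), and with 5 higher without IA replicate 1 or MetSA replicate 3. Within it Hmox1, the heme oxygenase, fell by 0.72 (SE 0.09, adjusted p = 4.82e-06 in edgeR's test) and Gclc, the catalytic subunit of glutathione synthesis, by 0.53 (SE 0.07), whereas the ferritin heavy chain Fth1 rose by 0.40. The list of ATF4 and the integrated stress response split into 10 higher and 10 lower of 34, or 11 and 10 adjusted over the list alone (median 0.09, camera adjusted p = 0.694). Without IA replicate 3 the lower count was 6. Across all genes, IA against M gave 4961 calls, 2524 higher and 2437 lower, of which 1127 changed at least 2-fold. The higher share was 50.9% with TMM and 34.8% with upper-quartile scaling.

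**Figure D2:**
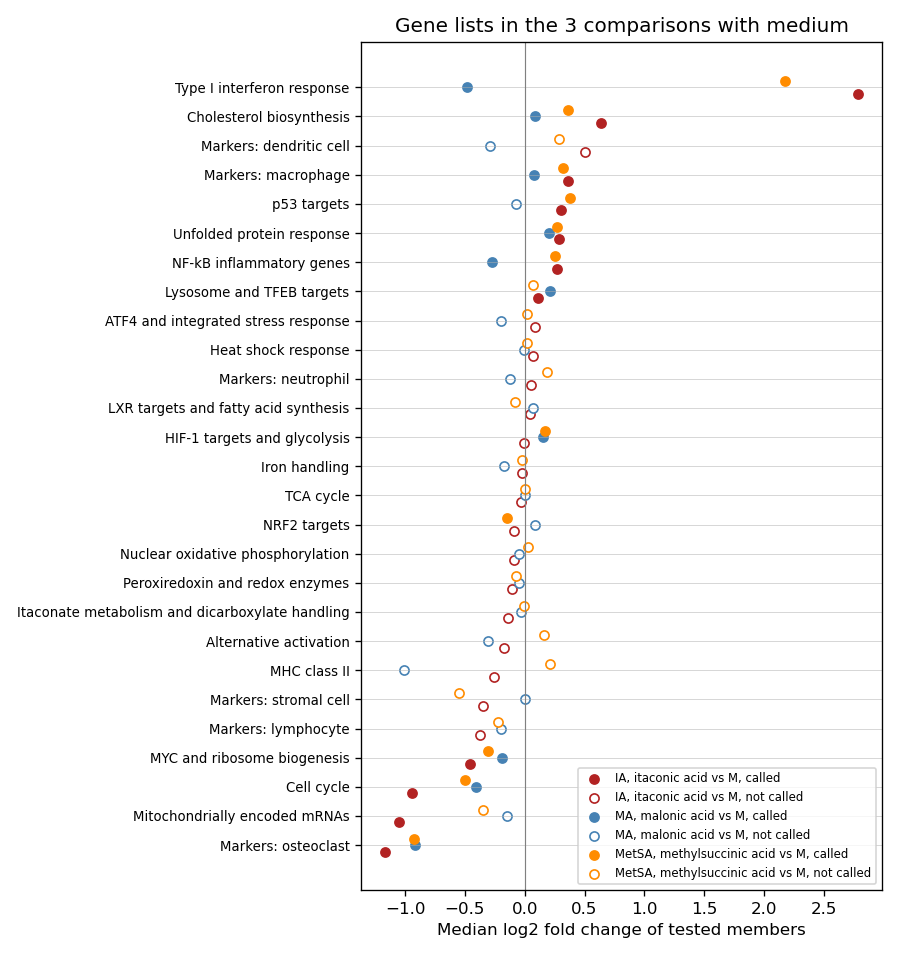
Median log2 fold change against M of the tested members of each gene list for IA, MA and MetSA, with filled points for lists called by camera at an adjusted p under 0.05 with its preset correlation and open points for the others. The interferon list lies at 2.79 for IA, 2.18 for MetSA and -0.48 for MA.

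The comparison of MA with M asked what a shorter dicarboxylic acid does at the same dose and time. Its largest rise among annotated genes at 10 CPM or more was Pmepa1, a membrane protein known as a target and a feedback inhibitor of TGF-beta signalling. It went from 0.663 ± 0.15 to 27.0 ± 1.1 CPM (n = 3, log2 fold change 5.34, SE 0.18, adjusted p = 9.53e-14 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene lies on chromosome 2 from 173224458 to 173276533 in mm10. Nt5e, the ectoenzyme CD73 that makes adenosine, rose from 0.746 ± 0.23 to 17.3 ± 2.5 CPM (4.53, SE 0.23, adjusted p = 5.26e-11). The junctional adhesion molecule F11r rose from 3.65 ± 0.97 to 50.5 ± 6.2 CPM (3.79, SE 0.16, adjusted p = 8.4e-11), and the caveolin Cav1 from 14.7 ± 2.6 to 105 ± 6.3 CPM (2.84, SE 0.26, adjusted p = 5.29e-05). The largest fall by the same rule was the protein kinase gene Dmpk, from 27.7 ± 2.2 to 2.64 ± 0.061 CPM (-3.39, SE 0.12, adjusted p = 3.53e-13). Its neighbour Dmwd on the same strand of chromosome 7 fell by 2.51 (SE 0.12). Mmp9 fell by 2.72 (SE 0.17), Dcstamp by 2.35 (SE 0.17) and the lectin Clec10a by 2.24 (SE 0.31).

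The interferon list fell after MA, with 18 of 33 members lower and none higher, or 23 lower adjusted over the list alone, at a median of -0.48 (camera adjusted p = 3.26e-08, and adjusted p = 0.534 with an estimated correlation). The lower count was 10 without M replicate 2 or MA replicate 2 and 9 without M replicate 3 or MA replicate 1. The antiviral oligoadenylate synthetase Oas2 fell by 0.76 (SE 0.12) and Ddx58 by 0.42 (SE 0.08). Inflammatory NF-kB genes also fell on balance, 14 of 33 lower and 4 higher, or 14 and 5 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.00502, and adjusted p = 0.4 with an estimated correlation). Il10 fell from 2.93 ± 0.61 to 0.498 ± 0.069 CPM (log2 fold change -2.55, SE 0.20), Nfkbiz by 0.87 (SE 0.08) and Tnf by 0.53 (SE 0.09), against a rise of the receptor Tlr2 by 0.74 (SE 0.08). Cell cycle genes fell, 21 of 36 or 25 adjusted over the list alone, at a median of -0.41 (camera adjusted p = 4.45e-09, and adjusted p = 0.4 with an estimated correlation). The DNA replication helicase subunits Mcm5 (-0.94, SE 0.10) and Mcm2 (-0.72) were among them. For MYC and ribosome biogenesis 7 of 22 were lower, also 7 adjusted over the list alone (median -0.19, camera adjusted p = 0.00425, and adjusted p = 0.4 with an estimated correlation), and 4 without M replicate 1 or MA replicate 2. Osteoclast markers had 4 of 7 lower and 1 higher, also adjusted over the list alone (median -0.92, camera adjusted p = 0.0176, and adjusted p = 0.4 with an estimated correlation).

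Lysosomal genes rose after MA, 16 of 30 higher and 2 lower, or 17 and 3 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.000111, and adjusted p = 0.4 with an estimated correlation). The lysosomal protease Ctsd rose by 0.81 (SE 0.07) on the log2 scale, though 30.2% of its sequence also occurs in another gene. HIF-1 targets and glycolysis had 12 of 33 higher and 3 lower, or 16 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.00156, and adjusted p = 0.4 with an estimated correlation). The hexokinase Hk2 rose from 45.7 ± 1.4 to 111 ± 5.6 CPM (1.28, SE 0.07). The unfolded protein response had 10 of 21 higher and 1 lower, or 11 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.00162, and adjusted p = 0.4 with an estimated correlation). Cholesterol biosynthesis had 7 of 26 higher, also 7 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.0397, and adjusted p = 0.583 with an estimated correlation). This call was lost without M replicate 2 (0.0782, median 0.05), M replicate 3 (0.0562), MA replicate 1 (0.139, median 0.05) or MetSA replicate 3 (0.0523), under the stricter filter (0.0531) and with fry (0.0525). Without MA replicate 2 the median was 0.14. Macrophage markers had 5 of 16 higher and 2 lower, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0306, and adjusted p = 0.4 with an estimated correlation). That call was lost without M replicate 1 (0.0779, median 0.05) or MA replicate 3 (0.062) and under the stricter filter (0.0506). The NRF2 list was not called (6 of 30 higher and 2 lower, or 8 and 4 adjusted over the list alone, median 0.09, camera adjusted p = 0.186), and 6 were lower without MetSA replicate 3. Within it the cystine transporter Slc7a11 rose by 1.42 (SE 0.28, adjusted p = 0.00111) and the glutathione transferase Mgst1 by 1.10 (SE 0.12). MHC class II genes were not called as a list (2 of 9 higher and 5 lower, also adjusted over the list alone, median -1.01, camera adjusted p = 0.16), and none was higher without M replicate 1 or MA replicate 3. With the replicate number as a block that list was called lower (camera adjusted p = 0.035). The invariant chain gene Cd74 fell from 167 ± 33 to 64.5 ± 9.2 CPM (-1.37, SE 0.19, adjusted p = 0.000813). MA against M gave 2860 calls over all genes, 1429 higher and 1431 lower, of which 528 changed at least 2-fold.

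The comparison of MetSA with M asked what the itaconic acid skeleton does without its double bond. Interferon-stimulated genes again led the rises. Slfn1 went from 2.42 ± 0.80 to 50.4 ± 19 CPM (n = 3, log2 fold change 4.37, SE 0.39, adjusted p = 4.99e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ifi44 rose from 7.73 ± 1.9 to 140 ± 44 CPM (4.18, SE 0.28, adjusted p = 6.63e-06) and Iigp1 by 3.84 (SE 0.33). The largest falls included Ifi27 (-1.54, SE 0.26, adjusted p = 0.00255), Dcstamp (-1.45, SE 0.17, adjusted p = 4e-05), Egr2 (-1.27, SE 0.11, adjusted p = 4.31e-08) and the metalloelastase Mmp12 (-1.09, SE 0.22, adjusted p = 0.00732). All 33 interferon list members rose, also adjusted over the list alone, with a median of 2.18 (camera adjusted p = 1.51e-37, and adjusted p = 0.0945 with an estimated correlation). The mean score of that list per library, in log2 units above the M mean, was 2.53, 2.31 and 1.93 in MetSA replicates 1 to 3 and 2.87, 3.00 and 2.99 in IA replicates 1 to 3. Without MetSA replicate 3 the list median was 2.31.

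NF-kB genes rose after MetSA, 15 of 33 with none lower, also adjusted over the list alone (median 0.25, camera adjusted p = 3.78e-06, and adjusted p = 0.0386 with an estimated correlation). Il1b, a central inflammatory cytokine, rose by 1.51 (SE 0.20, adjusted p = 7.21e-05 in edgeR's test), Il10 by 1.36 (SE 0.16) and Nfkbiz by 0.92 (SE 0.08). Macrophage markers had 11 of 16 higher, or 13 adjusted over the list alone (median 0.32, camera adjusted p = 3.87e-06, and adjusted p = 0.0386 with an estimated correlation). Fcgr1 rose from 307 ± 32 to 1160 ± 240 CPM (1.91, SE 0.13). Cholesterol biosynthesis had 18 of 26 higher and none lower, or 19 adjusted over the list alone (median 0.36, camera adjusted p = 5.71e-10, and adjusted p = 0.0945 with an estimated correlation). Hmgcs1 rose by 0.70 (SE 0.08) and Cyp51 by 0.69 (SE 0.08). Cell cycle genes fell, 33 of 36, also adjusted over the list alone (median -0.50, camera adjusted p = 2.72e-14, and adjusted p = 0.113 with an estimated correlation). Ccna2 fell by 0.79 (SE 0.11). MYC and ribosome biogenesis had 15 of 22 lower, or 17 adjusted over the list alone (median -0.31, camera adjusted p = 5.84e-07, and adjusted p = 0.0945 with an estimated correlation). In the unfolded protein response 13 of 21 rose, or 16 adjusted over the list alone (median 0.27, camera adjusted p = 1.59e-06, and adjusted p = 0.114 with an estimated correlation), Hspa5 by 0.73 (SE 0.06).

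HIF-1 targets and glycolysis had 15 of 33 higher and 2 lower after MetSA, or 18 and 2 adjusted over the list alone (median 0.17, camera adjusted p = 2.33e-05, and adjusted p = 0.113 with an estimated correlation). Hk2 rose by 0.98 (SE 0.07). The p53 targets had 9 of 20 higher and 1 lower, or 11 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.000309, and adjusted p = 0.0945 with an estimated correlation). Pmaip1, which encodes the apoptosis regulator Noxa, rose by 0.83 (SE 0.09). Osteoclast markers had 4 of 7 lower and 1 higher, or 5 and 1 adjusted over the list alone (median -0.93, camera adjusted p = 0.00884, and adjusted p = 0.197 with an estimated correlation). NRF2 targets were lower as a list, with 6 of 30 lower and 1 higher, or 6 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.00338, and adjusted p = 0.703 with an estimated correlation). Fry gave an adjusted p of 0.0904 for it. Without MetSA replicate 3 its median was -0.25, with 14 lower and 2 higher (camera adjusted p = 2.3e-06). The thioredoxin reductase Txnrd1 fell by 0.63 (SE 0.08, adjusted p = 1.87e-05 in edgeR's test), Gclc by 0.60 (SE 0.07) and Hmox1 by 0.41 (SE 0.09), whereas Mgst1 rose by 0.48. Mitochondrially encoded mRNAs were not called (3 of 12 lower, or 4 adjusted over the list alone, median -0.35, camera adjusted p = 0.0816). That list was called lower without MetSA replicate 3 (6 members lower, median -0.33, adjusted p = 0.0023) or M replicate 1 (1 lower, 0.0295), under the stricter filter (0.00329) and with the length and GC correction (0.0285). Lysosomal genes were not called either (12 of 30 higher and 4 lower, also adjusted over the list alone, median 0.07, camera adjusted p = 0.0816), though they were without MetSA replicate 2 (0.0201), and 2 were lower without M replicate 1, IA replicate 3 or MetSA replicate 2. MetSA against M gave 2989 calls, 1785 higher and 1204 lower, of which 499 changed at least 2-fold. The higher share was 59.7% with TMM and 42.2% with upper-quartile scaling.

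**Figure D3:**
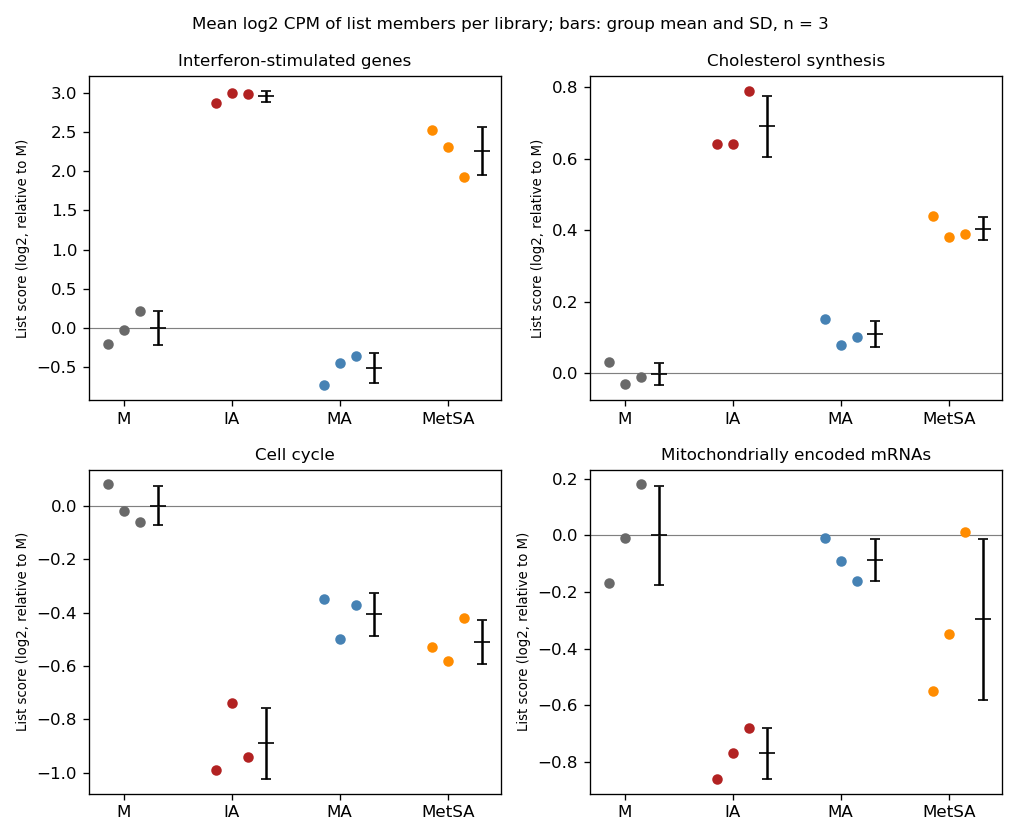
Mean log2 CPM of the tested members of 4 gene lists in each of the 12 libraries, in log2 units relative to the mean of M, with group mean and SD (n = 3) as bars. Interferon scores are 2.96 ± 0.073 in IA, 2.26 ± 0.30 in MetSA and -0.51 ± 0.20 in MA, and mitochondrial mRNA scores -0.77 ± 0.088 in IA.

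The responses to IA and MetSA overlapped. Of the genes called against M, 1606 were higher in both and 1016 lower in both, and none went opposite ways, where independent lists of these sizes would share 319 and 208. IA and MA shared 654 higher and 585 lower genes, against 256 and 247 for independent lists, and 445 genes went opposite ways, 316 of them up in IA and down in MA. MA and MetSA shared 482 higher and 399 lower genes, against 181 and 122, with 392 opposite. The same-direction count for MA and MetSA, 881, was 556 without M replicate 1. Simulated unchanged groups set against the shared M libraries gave 0.05 shared calls on average and 1 at most over 20 simulations. No gene was changed in these simulations, so few shared calls could arise. Groups that each had changes of their own were not simulated. Across the 14113 genes, which are not independent replicates, fold changes of IA and MetSA had a correlation of 0.84 and a covariance of 0.344, against 0.5 and 0.034 in the simulations, a difference in covariance of 0.31. For IA and MA the correlation was 0.26, below the simulated 0.5, and the covariance 0.101 (simulated 0.0336, difference 0.0671). For MA and MetSA they were 0.24, below the simulated 0.49, and 0.072 (simulated 0.0335, difference 0.0385). With 3 control libraries the controls could not be divided into parts of at least 2, so part of each excess may come from the shared controls. The simulated correlations come from noise and shared controls alone, so a value below them does not show that responses are unlike.

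**Figure D4:**
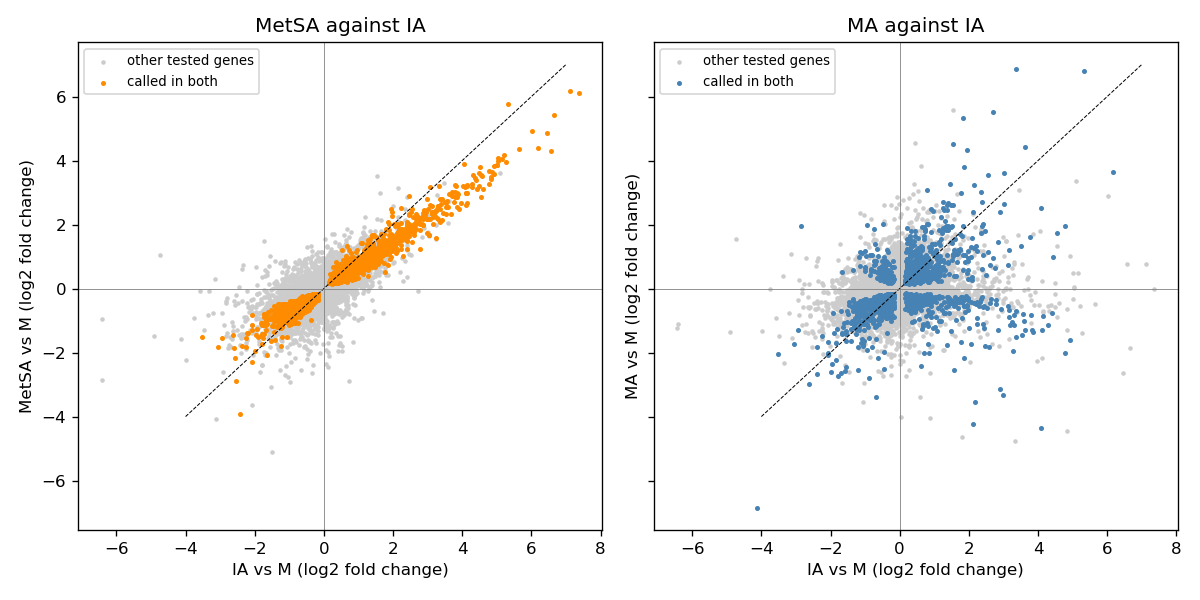
Log2 fold change against M of each of the 14113 tested genes after IA (horizontal axis) and after MetSA (left) or MA (right), with genes called in both comparisons in colour and the line of equal change dashed. None of the genes called in both IA and MetSA went opposite ways, and 445 of those called in both IA and MA did.

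Itaconic and methylsuccinic acid, which differ by the double bond, were compared directly at the same dose and time. Interferon-stimulated genes were higher after IA. Gbp6, a guanylate-binding protein gene, was at 59.6 ± 3.0 CPM in IA and 23.0 ± 8.4 in MetSA (n = 3, log2 difference 1.37, SE 0.24, adjusted p = 0.0106 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The transcription factor Pou3f1 was at 11.8 ± 0.87 and 4.79 ± 2.0 CPM (1.31, SE 0.24, adjusted p = 0.00511), and Ifih1 differed by 0.57 (SE 0.08, adjusted p = 0.00075). The value of Gbp6 is uncertain, since 64.5% of its 100-base stretches also occur in another gene. Ifit1bl1 showed the largest difference among genes at 10 CPM or more, 1.5 (SE 0.34, adjusted p = 0.0389). This call was lost without any of IA replicates 1 to 3 (0.0972, 0.0923 and 0.101), without MetSA replicate 2 (0.0952) or 3 (0.103), M replicate 2 (0.0585), or MA replicate 1 (0.0538) or 2 (0.0638). Acod1, the itaconate-making enzyme, was higher after IA by 1.20 (95% interval 0.69 to 1.70, adjusted p = 0.0115). Genes lower after IA than after MetSA included the mitotic genes Cdc20 (-0.94, SE 0.15, adjusted p = 0.00112) and Racgap1 (-0.71, SE 0.11, adjusted p = 0.00075), and Egr2 (-0.65, SE 0.11, adjusted p = 0.00174).

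As a list, 22 of 33 interferon genes were higher after IA than after MetSA, or 30 adjusted over the list alone, with a median difference of 0.61 (camera adjusted p = 1.95e-22, and adjusted p = 0.289 with an estimated correlation). Without MetSA replicate 3 the median was 0.51 with 11 genes higher, and the count was 13, 10 and 9 without IA replicates 1, 2 and 3 in turn and 10 without MetSA replicate 2. Cholesterol biosynthesis had 12 of 26 higher, or 18 adjusted over the list alone (median 0.28, camera adjusted p = 5.02e-12, and adjusted p = 0.152 with an estimated correlation). Idi1, an isoprenoid isomerase, was higher by 0.64 (SE 0.10). LXR targets and fatty acid synthesis had 3 of 21 higher, or 6 adjusted over the list alone (median 0.14, camera adjusted p = 0.00496, and adjusted p = 0.152 with an estimated correlation). The desaturase Scd2 was among them (0.51, SE 0.09), and their count was 6 without M replicate 3 and 1 without IA replicate 1. Cell cycle genes were lower after IA, 18 of 36 with 1 higher, or 25 and 1 adjusted over the list alone (median -0.39, camera adjusted p = 1.05e-11, and adjusted p = 0.289 with an estimated correlation). The lower count was 7 without IA replicate 1, 9 without IA replicate 3 and 10 without MetSA replicate 3. HIF-1 targets and glycolysis had 10 of 33 lower, or 18 lower and 3 higher adjusted over the list alone (median -0.17, camera adjusted p = 1.35e-06, and adjusted p = 0.163 with an estimated correlation). They included the pyruvate dehydrogenase kinase Pdk1 (-0.55, SE 0.07) and the glycolytic enzyme Pfkl (-0.41, SE 0.06), with 6 lower without IA replicate 1 and 5 without IA replicate 3. MYC and ribosome biogenesis had 2 of 22 lower, or 4 adjusted over the list alone (median -0.14, camera adjusted p = 0.0191, and adjusted p = 0.578 with an estimated correlation), a call lost without MetSA replicate 1 (0.0536). The count was 1 without IA replicate 1 or MetSA replicate 3 and 0 without IA replicate 3.

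Mitochondrially encoded mRNAs were called lower after IA than MetSA as a list with none of 12 members called, also adjusted over the list alone (median -0.53, camera adjusted p = 0.00182, and adjusted p = 0.537 with an estimated correlation). Without MetSA replicate 3 the median was -0.26, and without MetSA replicate 1 there was 1 member called. MHC class II genes had 1 of 9 lower, or 2 adjusted over the list alone (median -0.50, camera adjusted p = 0.0221, and adjusted p = 0.762 with an estimated correlation). That call was lost without IA replicate 1 (0.176) or MetSA replicate 3 (0.106, median -0.27), and no member was called without IA replicate 1 or 3 or MetSA replicate 2. Nuclear oxidative phosphorylation genes had no member called among 41, also adjusted over the list alone (median -0.11, camera adjusted p = 0.0472, and adjusted p = 0.816 with an estimated correlation). The list call was lost without M replicate 2 (0.0548), IA replicate 1 (0.504, median -0.07), MA replicate 3 (0.0522), MetSA replicate 1 (0.677, median -0.03) or MetSA replicate 2 (0.0507). It was also lost with RLE scaling (0.0521), the replicate number as a block (0.0506) and the length and GC correction (0.504). Without MetSA replicate 3 the median was -0.18 with 1 member called. Fry, which tests whether members move one way on balance, gave an adjusted p of 0.106 for the mitochondrial list, 0.266 for MHC class II, 0.485 for oxidative phosphorylation and 0.101 for MYC. Il1b, Nfkbiz, Tnf and Txnrd1 were not called between IA and MetSA. Il1b differed by 0.04 (95% interval -0.37 to 0.45, adjusted p = 0.936), and Nfkbiz by -0.14 (-0.32 to 0.03, adjusted p = 0.347). For Tnf the difference was 0.05 (-0.14 to 0.23, adjusted p = 0.827) and for Txnrd1 0.11 (-0.06 to 0.29, adjusted p = 0.479). These intervals bound the difference without showing that the compounds act alike. The NF-kB list had 5 of 33 higher and 2 lower, or 6 and 7 adjusted over the list alone (median -0.01, mean 0.21, camera adjusted p = 0.736). The higher count was 2 without IA replicate 1 or MetSA replicate 2 or 3, and 3 without M replicate 2 or 3, IA replicate 2 or MA replicate 1. NRF2 targets had 1 of 30 higher and 1 lower, or 4 and 1 adjusted over the list alone (median 0.10, camera adjusted p = 0.0698). They were called higher as a list without MetSA replicate 3 (6 higher and 0 lower, median 0.19, adjusted p = 4.31e-06) or IA replicate 1 (0.00693) and with the length and GC correction (0.0186).

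IA against MetSA gave 864 calls over all genes, 560 higher and 304 lower, of which 63 differed at least 2-fold. The higher share was 64.8% with TMM and 54.2% with upper-quartile scaling. Of the 1606 genes higher in both than in M, 398 were further from M in IA, 7 in MetSA and 1201 were not called between them, and of the 1016 lower in both the counts were 107, 1 and 908. The 864 calls became 426, 567 and 420 without IA replicates 1, 2 and 3 in turn, and 505 without MetSA replicate 3.

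Itaconic acid was next compared with malonic acid, the shorter dicarboxylic acid. Ifit1bl1 was at 311 ± 16 CPM in IA and 2.80 ± 1.0 in MA (n = 3, log2 difference 6.80, SE 0.46, adjusted p = 3.49e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Iigp1 was at 205 ± 17 and 2.24 ± 1.1 CPM (6.52, SE 0.39). Pmepa1 was lower in IA, at 2.39 ± 0.50 CPM against 27.0 ± 1.1 (-3.49, SE 0.15, adjusted p = 1.61e-12), as were Nt5e (-2.98, SE 0.21) and the proteoglycan Cspg4 (-2.57, SE 0.16). All 33 interferon genes were higher in IA, also adjusted over the list alone (median 3.27, camera adjusted p = 2.23e-34, and adjusted p = 0.155 with an estimated correlation). NF-kB genes had 20 of 33 higher and 2 lower, or 21 and 3 adjusted over the list alone (median 0.30, camera adjusted p = 1.07e-05, and adjusted p = 0.0838 with an estimated correlation). That median was 0.64 without IA replicate 2, 0.56 without IA replicate 3 and 0.66 without MA replicate 1. Il10 was higher by 4.13 (SE 0.20) and Il1b by 1.83 (SE 0.20). Cholesterol biosynthesis had 21 of 26 higher, or 22 adjusted over the list alone (median 0.54, camera adjusted p = 1.06e-10, and adjusted p = 0.106 with an estimated correlation). For p53 targets the counts were 15 of 20 higher and 1 lower, also adjusted over the list alone (median 0.47, camera adjusted p = 6.52e-05, and adjusted p = 0.106 with an estimated correlation).

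Cell cycle genes were lower in IA than in MA, 22 of 36 with 1 higher, also adjusted over the list alone (median -0.49, camera adjusted p = 1.7e-05, and adjusted p = 0.53 with an estimated correlation). So were MYC and ribosome biogenesis genes, 12 of 22 with 1 higher, or 13 and 1 adjusted over the list alone (median -0.28, camera adjusted p = 0.00535, and adjusted p = 0.524 with an estimated correlation). NRF2 targets had 11 of 30 lower and 2 higher, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0162, and adjusted p = 0.675 with an estimated correlation). The log2 difference was -1.02 for Slc7a11 (SE 0.27, adjusted p = 0.00724 in edgeR's test) and -0.69 for Hmox1. The NRF2 call was lost without IA replicate 1 (0.0636) or MA replicate 3 (0.0503). Mitochondrial mRNAs had 6 of 12 lower, or 7 adjusted over the list alone (median -0.86, camera adjusted p = 0.0156, and adjusted p = 0.655 with an estimated correlation), and 3 without IA replicate 1 or MA replicate 1. IA against MA gave 4887 calls, 2516 higher and 2371 lower, of which 1186 differed at least 2-fold, and the higher share was 51.5% with TMM and 37.5% with upper-quartile scaling.

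Malonic and methylsuccinic acid were compared at the same dose and time as well. Pmepa1 was at 27.0 ± 1.1 CPM in MA and 1.11 ± 0.17 in MetSA (n = 3, log2 difference 4.61, SE 0.17, adjusted p = 3.87e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Iigp1 was at 2.24 ± 1.1 and 96.6 ± 31 CPM (-5.44, SE 0.38). All 33 interferon genes were lower in MA, also adjusted over the list alone (median -2.63, camera adjusted p = 3.35e-35, and adjusted p = 0.196 with an estimated correlation). NF-kB genes had 25 of 33 lower and 1 higher, or 25 and 2 adjusted over the list alone (median -0.48, camera adjusted p = 9.02e-09, and adjusted p = 0.0195 with an estimated correlation). Il10 differed by -3.91 (SE 0.20) and the chemokine Ccl3 by -1.34. NRF2 targets were higher in MA, 16 of 30 with 1 lower, or 16 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 8.73e-05, and adjusted p = 0.597 with an estimated correlation). Among them were Txnrd1 (0.59, SE 0.08), Gclc (0.63, SE 0.07) and Slc7a11 (1.21, SE 0.28). MHC class II genes had 6 of 9 lower and 1 higher, or 7 and 1 adjusted over the list alone (median -1.24, camera adjusted p = 0.0117, and adjusted p = 0.597 with an estimated correlation). Cholesterol biosynthesis had 13 of 26 lower, also adjusted over the list alone (median -0.26, camera adjusted p = 3.03e-05, and adjusted p = 0.395 with an estimated correlation). The p53 targets had 13 of 20 lower and 1 higher, or 14 and 1 adjusted over the list alone (median -0.38, camera adjusted p = 0.000161, and adjusted p = 0.16 with an estimated correlation). MA against MetSA gave 3720 calls, 1640 higher and 2080 lower, of which 887 differed at least 2-fold, and the higher share was 44.1% with TMM and 54.5% with upper-quartile scaling.

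The series is titled for peroxiredoxin 5, a thioredoxin-dependent peroxidase of mitochondria, peroxisomes and cytosol. Its gene Prdx5 (chromosome 19, 6906697 to 6910106, mm10) was at 120 ± 9.9 CPM in M and rose in each of the 3 treated groups (n = 3 per group). It reached 207 ± 6.3 CPM in IA (log2 fold change 0.79, SE 0.08, adjusted p = 1.63e-07 in edgeR's test), 234 ± 14 in MA (0.97, SE 0.08, adjusted p = 1.73e-08) and 194 ± 21 in MetSA (0.70, SE 0.08, adjusted p = 1.71e-06). In sequence, 12.3% of its 100-base stretches also occur in another gene, so part of its count is uncertain. IA and MetSA differed by 0.09 in Prdx5 (95% interval -0.07 to 0.26, adjusted p = 0.541), and IA and MA by -0.18 (-0.34 to -0.02, adjusted p = 0.0786). MA was above MetSA by 0.27 (0.11 to 0.44, adjusted p = 0.0115), a call lost without MA replicate 3 (0.0669) or MetSA replicate 3 (0.055). The list of peroxiredoxins and redox enzymes was called in none of the comparisons with M by camera, with 5 of 27 higher and 6 lower in IA (adjusted p = 0.673), 6 and 5 in MA (0.859) and 6 and 5 in MetSA (0.575). Adjusted over the list alone these counts were 5 and 6, 6 and 6, and 6 and 6. The lower count in MA was 2 without M replicate 2 and 3 without M replicate 3, MA replicate 2 or any of the IA replicates, and in MetSA it was 3 without M replicate 2 or 3 or MetSA replicate 1 or 2.

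Acod1 (chromosome 14, 103046977 to 103056573) went from 2.26 ± 0.86 CPM in M to 26.0 ± 0.50 in IA (log2 fold change 3.52, SE 0.26, adjusted p = 7.73e-07 in edgeR's test). It reached 5.73 ± 0.80 CPM in MA (1.34, SE 0.27, adjusted p = 0.00381) and 11.4 ± 3.4 in MetSA (2.32, SE 0.26, adjusted p = 5.02e-05). Keap1, which encodes the sensor that holds NRF2 in check, rose by 0.92 (adjusted p = 1.88e-08) in IA and 0.58 (adjusted p = 1.31e-05) in MetSA and was at -0.02 in MA. For Nfe2l2, the gene of NRF2 itself, the log2 fold changes were 0.09, 0.02 and 0.14 in IA, MA and MetSA, and for Sdha, a succinate dehydrogenase subunit, 0.10, 0.01 and 0.11, none of them called. Il6 and Ifnb1 had too few counts to pass the filter. Ifnb1, the interferon beta gene, had 4, 8 and 4 counts in the IA libraries, 2, 8 and 10 in MetSA, 0, 2 and 0 in M and 0 in each MA library. In the same edgeR fit with no filter, chosen for these genes after seeing the data, Ifnb1 was above MA, where no library had a count, in IA (adjusted p = 0.0292) and in MetSA (0.025). Each Ifnb1 count was an even number, and with halved counts these values were 0.0412 and 0.0289. Against M it was not called in IA (0.218), MetSA (0.219) or MA (0.538), nor between IA and MetSA (1). Il6 had at most 8 counts in any library and was called in none of the 6 comparisons by edgeR with no filter, where its lowest unadjusted p was 0.0503.

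**Figure D5:**
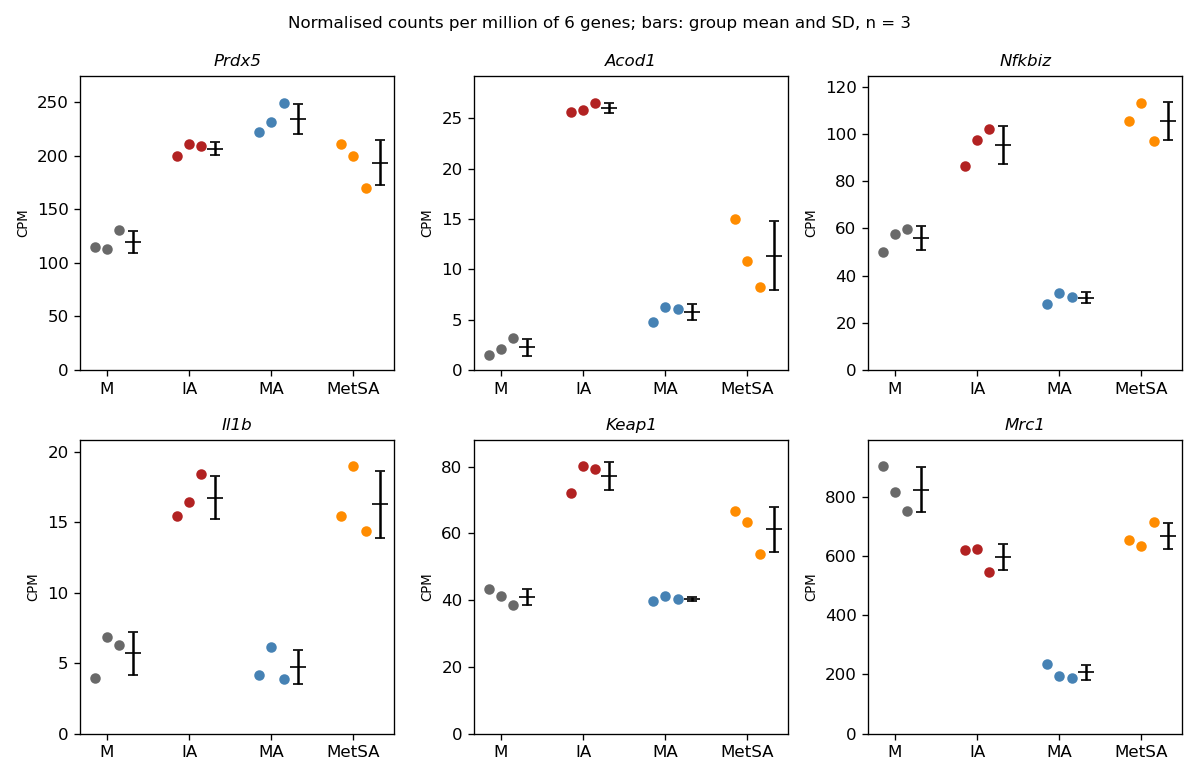
Normalised CPM of Prdx5, Acod1, Nfkbiz, Il1b, Keap1 and Mrc1 in each library, by group, with group mean and SD (n = 3) as bars and axes that start at 0. Prdx5 is at 120 ± 9.9 in M and between 194 and 234 on average in the treated groups, and Acod1 is at 26.0 ± 0.50 in IA.

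Genes that set 1 group apart from each of the other 3 were counted by requiring all 3 contrasts to be called in the same direction. IA stood apart in 598 genes, 431 higher and 167 lower, among them Gbp6 and Pou3f1 above and Cdc20, Plk1, Birc5 and Racgap1, which act in mitosis, below. For Plk1 the IA log2 differences were -1.29 to M, -0.99 to MA and -0.73 to MetSA (SE 0.13 each). The count was 325, 398 and 313 without IA replicates 1, 2 and 3 in turn, and 354 without MetSA replicate 3. MA stood apart in 1391 genes, 683 higher and 708 lower, with Pmepa1, Nt5e, Cspg4 and Cav1 above and Dmpk, Clec10a and Dmwd below. MetSA stood apart in 42 genes, 24 higher and 18 lower, including the chemokine Ccl6 at 274 CPM on average. Ccl6 was higher by 0.49 (SE 0.06) than in M, with log2 differences of -0.35 for IA and -1.78 for MA against MetSA. That count was 15 without IA replicate 1, 17 without IA replicate 3 and 23 without MetSA replicate 2. M stood apart from the 3 treated groups in 814 genes, 363 higher and 451 lower.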

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

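Halved counts, the length and GC correction, upper-quartile scaling for the list tests and the unfiltered fit for Il6 and Ifnb1 were added after seeing the data, and the others were planned. No called list or named gene changed sign, but with upper-quartile scaling the share of calls that were higher crossed 50.0% in IA against M (50.9% to 34.8%), MetSA against M (59.7% to 42.2%), IA against MA (51.5% to 37.5%) and MA against MetSA (44.1% to 54.5%). At an absolute log2 fold change of at least 1 the calls were 1127 for IA against M, 528 for MA against M, 499 for MetSA against M, 1186 for IA against MA, 63 for IA against MetSA and 887 for MA against MetSA. Genes apart were 41 for IA, 250 for MA and 0 for MetSA, which the threshold itself brings about. At an adjusted p under 0.01 they were 1786 for MA against M, 1852 for MetSA against M and 304 for IA against MetSA, with 228, 892 and 8 apart. IA against MetSA, the smallest contrast, also moved from 864 to 1483 with no filter, 1297 with DESeq2, 575 with only the compared groups and 1413 with the replicate block. Genes apart moved to 966 for IA and 96 for MetSA with no filter and to 104 for MetSA with the block, and the cause was not tested. Leaving out 1 library gave 420 to 974 for IA against MetSA, 313 to 683 for IA apart, 15 to 53 for MetSA apart and 556 to 901 for MA and MetSA shared, with fewer samples in each fit. Replicate numbers were not taken to pair the libraries, as 2 of 18 pairs of same-numbered libraries had residual correlations over 0.1. All 18 were above 0 (0.0122 to 0.169) and each of the 12 libraries correlated best with its own number. These values speak for a pairing by replicate number, though a weak one. The main calls therefore come from a fit that ignores a pairing the data make likely. With the block the other calls were 5507, 3262, 3527, 5380 and 4215. Calls lost with it were those of osteoclast markers in IA against M (adjusted p = 0.0596) and nuclear oxidative phosphorylation in IA against MetSA (0.0506). Calls gained were MHC class II in MA against M (0.035), MetSA against M (0.0338) and IA against MA (0.00827), iron handling in IA against MA (0.0241) and the unfolded protein response in MA against MetSA (0.0411). Among 162 list results, most of which were not called at first, 52 calls were lost with an estimated correlation. Those that held were 2 of 11 in MetSA against M, 1 of 6 in MA against MetSA and 0 in the other comparisons. With fry 6 calls were lost and 27 gained. Over the 12 fits that each left out 1 library, 21 list calls were lost and 29 gained, with 1894 results unchanged. Of 1051 named gene results 14 lost and 27 gained a call with upper-quartile scaling, 30 gained one with DESeq2, and fits without 1 library brought 405 losses. At the depth and replicate number of these libraries the simulation recovered 61.2% of 67 genes changed 1.5-fold. Far fewer genes were changed there than the 35.2% called in IA against M, which affects the adjusted p. The recovery need not hold for the real data, and what limits it was not tested. Low counts kept Il6 and Ifnb1 out of the main tests.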

Other observations

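Single macrophage surface and metabolic genes were also called in lists that were not called as a whole. After MA, 4 of 14 genes linked to alternative activation were higher and 6 lower, also adjusted over the list alone, with no call for the list (median -0.31, camera adjusted p = 0.443). The mannose receptor Mrc1 fell from 826 ± 75 to 207 ± 25 CPM (n = 3, log2 fold change -2.00, SE 0.09, adjusted p = 1.91e-11 in edgeR's quasi-likelihood test) and the haemoglobin scavenger receptor Cd163 by 1.73 (SE 0.20), while arginase 1 (Arg1) rose from 0.726 ± 0.27 to 4.42 ± 0.36 CPM (2.60, SE 0.32) and the transglutaminase Tgm2 by 1.46 (SE 0.07). After IA the list had 3 higher and 2 lower, also adjusted over the list alone, with a median of -0.17, a mean of 0.02 and an upward test (camera adjusted p = 0.966), and Tgm2 rose by 1.49 (SE 0.07). In the iron handling list MA had 2 of 14 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.103), and the iron exporter Slc40a1 fell from 251 ± 7.3 to 147 ± 3.9 CPM (-0.77, SE 0.09). Ceruloplasmin (Cp), a ferroxidase, rose by 1.89 (SE 0.20) after IA and 1.82 (SE 0.20) after MetSA. Slc13a3, a dicarboxylate transporter on the itaconate list, fell from 13.2 ± 1.5 to 4.75 ± 0.92 CPM after MA (-1.48, SE 0.14), and that list was not called in IA (camera adjusted p = 0.412), MA (0.547) or MetSA (0.786). Cx3cr1, the fractalkine receptor, was at 298 ± 68 CPM in IA and 976 ± 70 in MA (-1.71, SE 0.25).

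Of 11 dendritic cell markers 3 were higher after IA, or 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.304), but the chemokine receptor Xcr1 rose from 0.223 ± 0.055 to 4.86 ± 0.27 CPM (log2 fold change 4.42, SE 0.28, adjusted p = 3.59e-10 in edgeR's test). After MA and MetSA that list had camera adjusted p of 0.978 and 0.142, the latter 0.0286 without M replicate 3. The TCA cycle list had 1 of 22 higher and 6 lower after IA, also adjusted over the list alone (camera adjusted p = 0.448), among them the isocitrate dehydrogenase Idh2 (-0.70, SE 0.08), and gave 0.949 in MA and 0.575 in MetSA. Nuclear oxidative phosphorylation genes had 0 of 41 higher and 3 lower after IA, also adjusted over the list alone (camera adjusted p = 0.304). The lower count was 6 and 7 without MetSA replicates 1 and 3, and the list was called lower without M replicate 1 (0.0214). It gave 0.583 in MA and 0.886 in MetSA. LXR targets gave 0.448, 0.364 and 0.331 in IA, MA and MetSA, the heat shock list 0.651, 0.859 and 0.867, the neutrophil list 0.655, 0.949 and 0.415, the lymphocyte list 0.999, 0.874 and 0.786 and the stromal list 0.651, 0.859 and 0.415. The mast cell list had 2 members with enough counts and the erythroid list 0, so neither was tested.

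The tests of the mitochondrial and interferon patterns that follow were chosen after those results were seen, and the tests of the TGF-beta list and of regrouped libraries before.

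Mitochondrially encoded mRNAs were lower after IA than in M, from mt-Cytb at -1.63 to mt-Nd5 at -1.14 among the 6 called members, with a list median of -1.05 that was -0.48 without IA replicate 2. Reads shared with nuclear copies are argued against, because 5 members with under 10% of their sequence in another gene had a median of -1.18. The list median was -1.03 or lower with TMM, RLE and upper-quartile scaling, so the choice among these methods does not explain the fall. For IA against M the median log2 fold change of all genes was -0.031, -0.013 and -0.119 with these methods in turn. Switching among them could therefore hardly change the list result. A scaling error common to these methods was not tested and stays open. An equal loss of all mitochondrial RNA is argued against by mt-Co1 alone, at -0.05 (SE 0.15), which differed by 7.99 SE from the median of -1.23 of 6 other abundant members; 30.8% of its sequence also occurs in another gene, but 5 members with 90% or more shared had at most 203 counts in any library, against 251160 or more for mt-Co1, so shared stretches added little to its count. The same 6 members were lower after MetSA too, from mt-Cytb at -0.87 to mt-Nd5 at -0.59, with mt-Co1 at 0.06. Of these mt-Nd1, mt-Nd2 and mt-Cytb were called. After MA they ran from -0.47 to -0.08, none called. The pattern is thus not particular to IA. A change in particular mitochondrial transcripts after IA may be a biological effect of the compound. It remains a hypothesis, as RNA integrity was not measured here.

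Interferon genes rose after IA and MetSA. A trend with transcript length and GC content is argued against, since after its removal the list medians were 2.81 for IA and 2.13 for MetSA. Reads shared between paralogs are argued against, since 27 members with little shared sequence had medians of 2.93 and 2.21. Endotoxin in the compound stocks stays open. The NF-kB list, which endotoxin would raise, had medians of 0.27 for IA and 0.25 for MetSA. Its mean scores were 0.63 and 0.46 log2 units above M. No library with a known endotoxin dose was analysed here, so endotoxin cannot be told apart from an effect of the compounds. An effect of IA and MetSA on interferon signalling is thus a candidate explanation that these data leave open.

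Because Pmepa1, a known TGF-beta target, had the largest rise after MA among annotated genes at 10 CPM or more, a hypothesis was that MA raises TGF-beta signalling, tested on a list of 36 genes written after that rise was seen and before the list's own values were. Of the 35 tested, 14 were higher and 6 lower, with a median of 0.06 (interval -0.02 to 0.28), and camera gave p = 0.00237, or p = 0.0108 with an estimated correlation. The receptor Tgfbr1 rose by 1.43 and the feedback inhibitors Smad7 and Skil by 1.14 and 1.09, whereas Id1 fell by 1.76 and Id3 by 0.94. Skil also rose by 1.05 after IA and 0.66 after MetSA, where Tgfbr1 and Smad7 were not called higher. The median did not meet the rule set beforehand in either direction, so the hypothesis stays undecided.

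Each comparison of 3 against 3 libraries has 10 splits, so a share under 0.05 cannot be reached. The real split gave the most calls in each of the 6, being 1 of 10 with as many. The real counts were 4961 for IA against M, 2860 for MA against M, 2989 for MetSA against M, 4887 for IA against MA, 864 for IA against MetSA and 3720 for MA against MetSA, and the highest of the other splits in edgeR was 1 for MA against M and 0 for the rest. At an unadjusted p under 0.05 the highest others were 602, 858, 1139, 398, 949 and 1108, against 6176, 4318, 4565, 6042, 2858 and 5034. Among 40 regroupings of the 12 libraries, the real one gave the most genes that set MA apart (1391, highest other 0) and MetSA apart (42, highest other 0). It also gave the most shared calls of IA and MetSA (2622, highest other 139), IA and MA (1239, 352) and MA and MetSA (881, 144). Each was 1 of 40, the lowest share that 40 regroupings can give. Regrouping mixes libraries of different treatments, which widens the spread within groups, so low counts were likely beforehand. These counts therefore do not exclude chance, and they do not test sharing beyond the common controls. For IA apart, 3 of 40 gave as many genes as the real 598, the highest 641. In both other regroupings, with 641 and 633 genes, the libraries set apart were the 3 MA libraries. Those regroupings carry the difference of MA rather than a chance one, so this count cannot decide whether chance explains the genes that set IA apart.

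MetSA replicate 3 had a mean of 7.77 log2 CPM over the interferon list, against 8.36 and 8.15 in MetSA replicates 1 and 2. Its mt-Co1 level was 8237 CPM, and 11 of 8311 genes lay more than 1.5-fold outside the range of the M and other MetSA libraries, against 3 and 1 for the others.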
